A study of Mus musculus with 2 samples.

How the data were processed

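Colon nuclei of 15-week-old male C57BL/6 mice were profiled in 2 libraries, 1 of wild-type littermates and 1 of Pink1 knockout mice. Per the labels' protocols, the colon was flushed, opened and minced, nuclei were released by detergent and homogenisation, and nuclei stained with SYTOX Green were sorted into cold methanol. Nuclei of 3 mice per genotype were then pooled and run on the 10x Genomics platform with 3' tags, with a target of 10000 nuclei per library. The deposited values are UMI counts per gene and barcode, made with Cell Ranger 6.1.2 per the file headers, on mm10 (GRCm38) per the submitters' processing notes. The annotation release, the counting of introns and any removal of doublets are not given in the sources used here. The smallest barcode total in the files was 500 UMIs in both libraries. Gene coordinates came from GENCODE M21 of GRCm38, matched by gene ID for 32158 of 32285 IDs (99.6%), and 38 symbols were shared by more than 1 ID.

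Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 10% mitochondrial UMIs, which 8888 wild-type and 12146 knockout barcodes passed. Doublets were taken as the highest Scrublet scores in each library, at 0.8% per 1000 kept barcodes, which removed 632 wild-type (7.11%) and 1180 knockout barcodes (9.72%). Scrublet's own threshold called 435 (4.89%) and 954 (7.85%). The kept nuclei of both libraries were clustered jointly without integration: counts were scaled to 10000 UMIs and log-transformed, 2000 variable genes were reduced to 30 principal components, and a shared nearest neighbour graph with 20 neighbours was partitioned by the Leiden method at resolution 1, which gave 31 clusters. Mitochondrial, Xist, Y-linked and Pink1 counts were left out of the variable genes.

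Markers for 21 classes were fixed before the data were examined. The rule that turns markers into names was set after the data were seen: a cluster took the class with the highest mean log2 fold of its markers (5 CPM added) if that mean was at least 0.3 and at least 3 markers were 2-fold or more above the other clusters. Names gave 16 classes, and 3 epithelial clusters stayed unnamed (clusters 2, 5 and 11, led by Gsdmc3, Gk and Aqp4 among others). Leading genes were Plet1 and Muc2 in goblet-like cluster 0, Fer1l6 and Fcgbp in goblet-like cluster 10, Fut9 and Smoc2 in crypt-base cluster 1, Esco2 and Top2a in proliferating cluster 9, Slc10a2 in colonocyte-like cluster 6, Slc37a2 and Car4 in cluster 8, Slc9a3 and Ly6m in cluster 12, Clec3b and Dcn in fibroblast-like cluster 13, Des and Myh11 in smooth muscle-like cluster 14 and Cd163 and Mrc1 in macrophage and dendritic-like cluster 17. Immune or stress genes were among the 10 leading genes of colonocyte-like clusters 7 (Reg3b, Reg3g) and 8 (Saa1), goblet-like cluster 10 (Slfn4) and fibroblast-like clusters 13 (Serpina3n) and 16 (Ptgs2). A list's leading example was left out of the text where it was such a gene. The names are rebuilt from markers and may differ from those of the study.

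With 1 library per genotype there are no replicates, so no test was run between genotypes and no p-value is given. Shares of nuclei carry exact Clopper-Pearson 95% intervals, counts exact Poisson intervals and ratios exact conditional binomial intervals, all for counting error only. Counts were summed per library and class and expressed as CPM over nuclear-encoded genes. A count of 0 was set against a floor of 3 counts, which is 0.199 CPM over all wild-type and 0.162 CPM over all knockout nuclei. Classes needed at least 100 nuclei in each library and genes at least 50 counts in the class. For 32 gene lists fixed before the data were examined, the median log2 ratio of members with at least 20 counts (0.5 added to each count) was set against 10000 random lists of the same size matched on mean expression, where at least 5 members were measured. The number of genes at least 2-fold apart had been planned as a description of the libraries. It is left out because a count of changed genes made from cells of 1 library per genotype has no replicate behind it.

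The genes named were chosen by a rule fixed before the data were examined. It took Pink1, and in each of the 6 classes with the most nuclei the 4 genes highest and the 4 lowest in the knockout library by the bound of the ratio's interval nearest to 1, leaving out mitochondrial, Xist, Y-linked, immunoglobulin and hemoglobin genes and class markers. It added the 5 genes highest and the 5 lowest by median log2 ratio among genes at least 1.5-fold apart in 1 direction in every class with 50 counts, with at least 4 such classes, and members of the lists described. Genes named only as clones were replaced by the next named gene. Some genes that the rule takes are not reported here.

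Alternatives fixed before the data were examined were a looser filter (300 UMIs, 200 genes, no mitochondrial limit), a stricter one (1000 UMIs, 600 genes, 2% mitochondrial), no doublet removal, Scrublet's own threshold, Leiden resolutions of 0.5 and 2, separate clustering of the libraries, TMM factors, median-of-ratios factors, subtraction of 10% free RNA, other count minimums, nuclei thinned to 500 UMIs, and shares within a compartment. Another 2 were added after seeing the data: CPM without Malat1 and the rRNA-like transcripts Gm42418, Gm26917 and AY036118, and gene lists in nuclei without a mitochondrial UMI. The list medians over all nuclei were not put through the alternatives. Random lists were not redrawn under the alternatives, whose medians were set against the random range of the reported setting.

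The ratios, their intervals and the list percentiles were tested on simulated data drawn from the summed counts of all barcodes that passed the filter. The sums were scaled to the depth of a large class (4228621 and 5550492 UMIs) and a small one (253717 and 333029 UMIs). Counts were drawn as Poisson counts, which the intervals assume, so the test checks the computation and not clumping of counts in single nuclei. Filtering, doublet removal, clustering and naming were not tested. In the large class the 95% intervals held the true ratio for 95.5% of 11589 unchanged genes and 95.5% of 66 genes set 1.5-fold apart, all 66 of which had the right direction. In the small class they held it for 96.0% of 2272 unchanged genes and 93.3% of 60 genes set 1.5-fold apart, of which 90.0% had the right direction. Of 200 unchanged lists, 5.5% in the large and 5% in the small class fell outside the central 95% of random lists. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, R 4.3.3 and edgeR 4.0.16, which gave the TMM factors.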

Results

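Single-nucleus RNA sequencing compared the colon of 15-week-old male Pink1 knockout mice with that of wild-type littermates on the C57BL/6 background. Pink1 encodes a kinase that marks damaged mitochondria for removal. Each genotype was represented by 1 library, made from the sorted nuclei of 3 mice pooled before loading, so no value has a replicate check and no test between genotypes was possible. The wild-type library held 8924 barcodes and 16997995 UMIs, and the knockout library 12230 barcodes and 22446326 UMIs. After filtering, 8256 wild-type nuclei with a median of 1626 UMIs and 1003 genes and 10966 knockout nuclei with a median of 1570 UMIs and 964 genes were kept. All intervals in parentheses are 95% intervals that cover counting error only, not the variation between mice, and ratios are knockout over wild-type library. Genotype, library and the batch given in the labels (1 for wild type, 2 for knockout) coincided, so they cannot be told apart.

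The Pink1 transcript (ENSMUSG00000028756; GRCm38, chromosome 4, 138313409 to 138326307) was lower in the knockout library but was not absent. Over all nuclei it had 170 and 113 counts in the wild-type and knockout libraries, or 11.3 and 6.1 CPM (counts scaled to a common total, over nuclear-encoded genes), a ratio of 0.541 (0.422 to 0.690). In goblet-like nuclei the ratio was 0.444 (0.246 to 0.777), from 40 and 20 counts (0.238 with nuclei thinned to 500 UMIs), in crypt-base and proliferating nuclei 0.507 (0.268 to 0.930) and in colonocyte-like nuclei 0.583 (0.337 to 1.00). Fibroblast-like nuclei had 10 and 13 counts, smooth muscle-like nuclei 5 and 1, and macrophage and dendritic-like nuclei 2 in each library. The deleted part of the gene is not given in the sources used here, and 3' tags that lie outside it check nothing about the label.

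**Figure D1:**
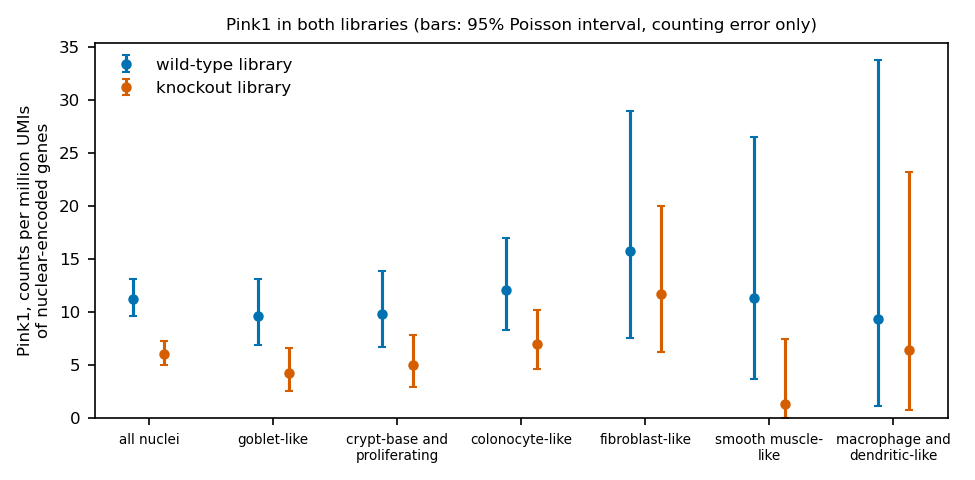
Pink1 CPM over nuclear-encoded genes in each library, over all nuclei and in 6 classes, with 95% Poisson intervals for counting error only. Over all nuclei the wild-type library stood at 11.3 and the knockout library at 6.1.

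The first comparison asked whether the make-up of the colon differed between the libraries. B-like nuclei were scarcer in the knockout library, at 1.17% of wild-type and 0.328% of knockout nuclei (97 and 36), a ratio of 0.279 (0.185 to 0.414). Plasma-like nuclei had a higher share there, with a ratio of 1.76 (1.17 to 2.70), as did blood endothelium-like nuclei at 1.73 (1.30 to 2.32), fibroblast-like nuclei at 1.45 (1.29 to 1.64), smooth muscle-like nuclei at 1.34 (1.16 to 1.55) and macrophage and dendritic-like nuclei at 1.30 (1.06 to 1.59). Within the epithelium, colonocyte-like nuclei made up 16.9% of wild-type and 20.7% of knockout nuclei (1399 and 2265), a ratio of 1.22 (1.14 to 1.30), goblet-like nuclei had a ratio of 0.903 (0.850 to 0.959) and crypt-base and proliferating nuclei one of 0.912 (0.856 to 0.971). Enteric neuron-like nuclei numbered 16 and 4, a ratio of 0.188 (0.0458 to 0.583). The intervals for T and innate lymphoid-like, enteric glia-like, enteroendocrine-like, interstitial cell of Cajal-like, lymphatic endothelium-like and tuft-like nuclei included 1. The named epithelial classes together took 64.1% and 63.6% of nuclei and all stroma with muscle 9.41% and 13.1%.

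Nuclei were sorted on a DNA stain, and shares depend on isolation and sorting as well as on the tissue. The B-like nuclei had no class of their own in the knockout library when the libraries were clustered separately, and the enteric neuron-like ratio was 1.20 with a looser filter and 1.12 at resolution 0.5. With the stricter filter the B-like ratio was 0.518. Within compartments the fibroblast-like, smooth muscle-like and blood endothelium-like ratios were 1.04, 0.959 and 1.18, so for fibroblast-like and smooth muscle-like nuclei the direction is that of the whole stroma with muscle. None of the 3 epithelial ratios kept its direction. The goblet-like ratio was 1.58 with separate clustering, the colonocyte-like one 0.976 at resolution 2 and the crypt-base and proliferating one 1.04 with the stricter filter and 1.07 at resolution 2. A further 19.3% of wild-type and 15.1% of knockout nuclei lay in 3 epithelial clusters that met no class's marker rule. Cluster 5 held 13.3% of the wild-type nuclei and 0.584% of the knockout nuclei, and cluster 2 held 1.33% and 10.6%. Each was the other's nearest cluster, and with 1 library per genotype a cluster mostly of 1 library cannot be told apart from that library.

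**Figure D2:**
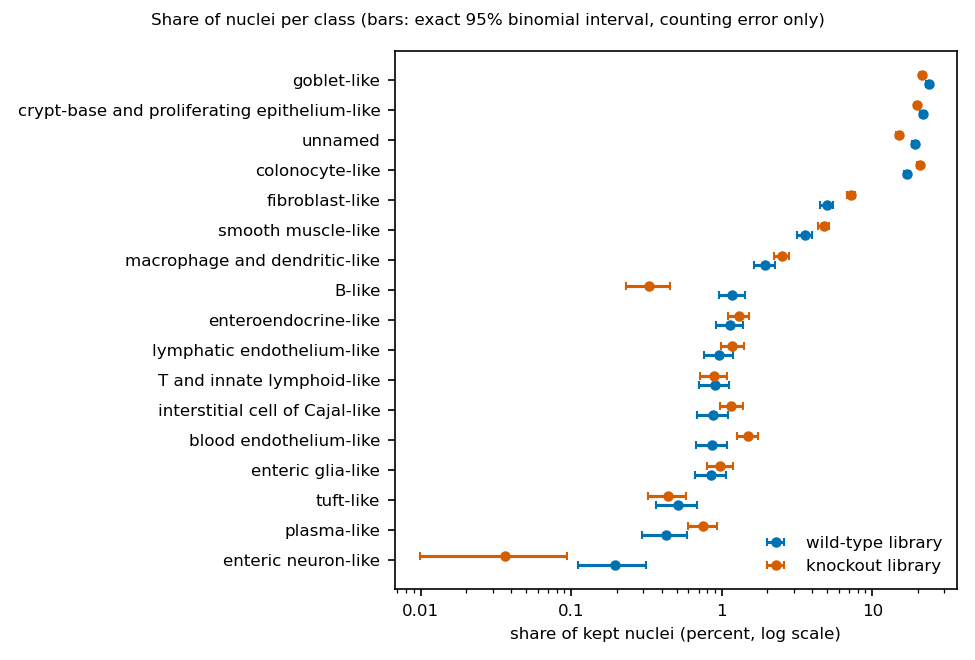
Share of kept nuclei in each class (percent, log scale) in the wild-type and knockout libraries, with exact 95% binomial intervals for counting error only. B-like and enteric neuron-like nuclei had lower shares in the knockout library, and fibroblast-like, blood endothelium-like and plasma-like nuclei higher ones.

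The second comparison asked which genes differed within each class, in the 6 classes with the most nuclei. Immediate early genes, which cells switch on within minutes of a stimulus, were higher in the knockout library in all 6 classes. Egr1, a zinc finger transcription factor (ENSMUSG00000038418; chromosome 18, 34859823 to 34864984), had 27 and 4241 counts in goblet-like nuclei, a ratio of 139 (95.7 to 212). Its ratio was 47.3 (38.1 to 59.4) in crypt-base and proliferating, 9.15 (7.77 to 10.9) in colonocyte-like, 15.7 (12.7 to 19.7) in fibroblast-like and 52.2 (29.8 to 101) in smooth muscle-like nuclei. Over the alternatives the Egr1 ratio ran from 56.5 to 283 in goblet-like and from 6.11 to 14.0 in colonocyte-like nuclei. With the stricter filter it was 10.4 in fibroblast-like and 109 in smooth muscle-like nuclei. Fos, a subunit of the AP-1 transcription factor, had ratios of 9.44 (8.14 to 11) in goblet-like (5.71 with separate clustering), 12.4 (9.93 to 15.7) in crypt-base and proliferating, 4.67 (4.22 to 5.18) in colonocyte-like, 18.2 (10.3 to 35.6) in fibroblast-like (32.4 in nuclei thinned to 500 UMIs), 16.6 (9.17 to 33.7) in smooth muscle-like and 28.2 (10.8 to 105) in macrophage and dendritic-like nuclei (12.9 without doublet removal). Among 18 measured members of the list in goblet-like nuclei, 17 were at least 1.5-fold higher, none was as much lower, and 1 lay between. In crypt-base and proliferating nuclei 12 of 18 were higher and 1 lower, in colonocyte-like nuclei 16 of 19 were higher, in fibroblast-like nuclei 18 of 21, in smooth muscle-like nuclei 17 of 19 and in macrophage and dendritic-like nuclei 12 of 13.

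The median log2 ratio of the immediate early list was 1.84, 1.19, 0.96, 2.31, 2.13 and 1.44 in goblet-like, crypt-base and proliferating, colonocyte-like, fibroblast-like, smooth muscle-like and macrophage and dendritic-like nuclei. Each median stood at percentile 100 among 10000 random lists of the same size matched on mean expression, as a description of these libraries. With each nucleus thinned to 500 UMIs, which left none out, an Egr1 UMI was found in 0.459% of wild-type and 30.3% of knockout goblet-like nuclei, against 0.969% and 57.6% unthinned at median depths of 1956 and 1844.5 UMIs. In macrophage and dendritic-like nuclei the thinned shares were 1.89% of wild-type and 5.11% of knockout nuclei, and the unthinned ones 3.77% and 8.39% at median depths of 1167 and 1065 UMIs. Any class can express Egr1, so Muc2, the goblet cell mucin, gives the level of free RNA. Smooth muscle-like nuclei had it in 24.5% of wild-type and 15.7% of knockout nuclei at 500 UMIs, and in 49.3% and 39.2% unthinned at median depths of 1217 and 1275 UMIs.

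In goblet-like nuclei, the mucus-secreting cells of the epithelium, Ly6m, a member of the Ly6 family, had a ratio of 15.2 (9.70 to 25.2) and Sgk1, a kinase that regulates sodium transport, one of 11.3 (8.88 to 14.7). Lower in the knockout library were the zinc finger gene Zfp990 at 0.0370 (0.00435 to 0.141) from 48 and 2 counts, Rims2, which acts in vesicle release, at 0.293 (0.222 to 0.384), and the antisense transcript H3f3aos at 0.279 (0.164 to 0.456). Of 24 mucus and secretory genes, 6 were at least 1.5-fold higher and none as much lower, with a median log2 ratio of 0.24 (percentile 100). Xbp1, a transcription factor of secretory cells, had a ratio of 1.74 (1.63 to 1.86) and Zg16, a lectin of the mucus, 1.61 (1.57 to 1.65), while Atoh1, which specifies secretory cells, had 0.711 (0.654 to 0.773). Of 28 junction genes 2 were higher, Cldn4 at 3.97 (2.88 to 5.56) and Cldn3 at 1.85 (1.59 to 2.17), and 26 lay within 1.5-fold. Zfp990 belongs to a family of closely similar genes, and whether the authors' counting used strand is not given in the sources used here, so both it and H3f3aos are uncertain. The Zfp990 ratio was 0.0752 at resolution 2 and 0.0146 without doublet removal, with no knockout count left in thinned nuclei. Zg16 was among the leading genes of cluster 10, which held 315 of 1961 wild-type and 541 of 2352 knockout nuclei of the class, against 637 and 570 in cluster 4, so these values also carry the mix of clusters. The Ly6m ratio was 8.04 with separate clustering, the Sgk1 one 18.3 at resolution 2 and the Rims2 one 0.514 in nuclei thinned to 500 UMIs.

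In crypt-base and proliferating nuclei, which hold the stem and dividing cells, Hbegf, a ligand of the epidermal growth factor receptor, had a ratio of 8.64 (6.67 to 11.4) and the interferon-induced GTPase Iigp1 one of 6.35 (3.96 to 10.7), but 3.68 at resolution 0.5 and 3.06 in thinned nuclei. Zfp990 had 163 and 3 counts, a ratio of 0.0166 (0.00338 to 0.0493), and Zfp979, of the same gene family, 53 and 1 counts, a ratio of 0.0170 (0.000422 to 0.0989), with no knockout count of Zfp979 left and a Zfp990 ratio of 0.0258 in thinned nuclei. Rims2 had a ratio of 0.321 (0.249 to 0.411) and Tef, a clock-controlled transcription factor, 0.304 (0.217 to 0.421). Of 35 cell cycle genes, 34 lay within 1.5-fold and 1 was higher, with a median log2 ratio of 0.14 (percentile 99.7). Ezh2, a histone methyltransferase, had a ratio of 1.38 (1.23 to 1.53) and the kinetochore protein Cenpf 0.721 (0.670 to 0.775). The cell cycle median was -0.025 with the stricter filter and -0.057 at resolution 2, and 0.082 with Scrublet's own threshold, all 3 inside the random range. Of 13 Wnt target and stem cell genes 12 lay within 1.5-fold, and Ccnd1, which encodes cyclin D1, had a ratio of 1.56 (1.30 to 1.87). The antioxidant enzyme gene Gpx2 had a ratio of 2.20 (2.00 to 2.42). Of 6 MHC class II genes, which present antigen, 5 were at least 1.5-fold higher, with a median log2 ratio of 1.03 (percentile 100), H2-Aa at 2.88 (1.38 to 6.57) from 10 and 32 counts.

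In colonocyte-like nuclei, the absorptive cells, Sgk1 had a ratio of 6.31 (5.69 to 7.01), Ly6m 7.33 (5.57 to 9.83) and Iigp1 9.62 (4.23 to 27.0), although 60.5% of the knockout counts of Iigp1 lay in 1 nucleus and its ratio was 0.414 at the finer and 1.52 at the coarser clustering, and 24.4 with 10% free RNA subtracted. Lower in the knockout library were Gal3st2c, of a sulfotransferase family, at 0.0814 (0.0338 to 0.169) from 70 and 8 counts, the clock-controlled transcription factor Dbp at 0.0737 (0.0260 to 0.170) (0.169 in thinned nuclei and 0.117 without doublet removal), Rims2 at 0.199 (0.142 to 0.274) and Edn1, which encodes endothelin 1, at 0.270 (0.221 to 0.329). Of 24 ion and water transport genes 3 were at least 1.5-fold higher and 4 as much lower. The potassium channel gene Kcnn4 had a ratio of 2.94 (1.68 to 5.44), the carbonic anhydrase gene Car2 0.533 (0.493 to 0.576) and the bicarbonate cotransporter gene Slc4a4 0.596 (0.539 to 0.660). Of 16 glycolysis genes 15 lay within 1.5-fold, and Pdk1, a kinase that restrains pyruvate dehydrogenase, had 0.350 (0.274 to 0.444). Gal3st2c was a leading gene of goblet-like cluster 4, 40% of its wild-type and 62.5% of its knockout counts lay in 1 nucleus, and no knockout count was left with 10% free RNA subtracted. The largest part of this class was cluster 8 in the wild-type library (38.0%) and cluster 6 in the knockout library (30.5%), and Ly6m was among the 10 leading genes of cluster 12, so these values also carry the mix of clusters.

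In fibroblast-like nuclei, Errfi1, a feedback inhibitor of the epidermal growth factor receptor, had 39 and 2525 counts, a ratio of 37.0 (27.0 to 52.2), and the nuclear receptor Nr4a1 had 23.1 (12.4 to 48.4). Lower in the knockout library were the transcription factors Tcf21 at 0.333 (0.257 to 0.428) (0.206 in thinned nuclei) and Zbtb16 at 0.393 (0.320 to 0.482), the membrane protein Slitrk6 at 0.40 (0.266 to 0.597) and the RNA-binding protein Hnrnpr at 0.542 (0.475 to 0.618). Of 27 extracellular matrix and fibrosis genes 5 were at least 1.5-fold higher and none as much lower (median log2 ratio 0.15, percentile 97.3). That median, 0.147, lay inside a random range that ended at 0.152. It lay above that range at 0.168 with the looser and 0.186 with the stricter filter. So it did at 0.185 with Scrublet's own threshold and 0.171 in nuclei without a mitochondrial UMI. The remaining settings that do not shift all ratios alike left it inside. The matricellular protein Ccn1 had a ratio of 4.84 (3.79 to 6.25) and Postn, which encodes periostin, 0.905 (0.835 to 0.981).

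In smooth muscle-like nuclei, Nr4a1 had a ratio of 36.9 (18.6 to 86.0), the small GTPase Arl4d 27.1 (13 to 67.9) (16.2 in thinned nuclei) and Errfi1 18.9 (12.6 to 29.7). Lower in the knockout library were Ptprz1, a receptor phosphatase, at 0.342 (0.229 to 0.505) (0.519 with the stricter filter), Zbtb16 at 0.499 (0.397 to 0.627), the pentraxin Mptx1 at 0.144 (0.0859 to 0.231) and the sulfate transporter Slc26a2 at 0.408 (0.240 to 0.683). Of the wild-type counts of Mptx1, 72.2% lay in 1 nucleus, it was a leading gene of goblet-like cluster 4, and its ratio was 0.517 with the looser and 0.687 with the stricter filter. The Slc26a2 ratio was 1.00 without doublet removal, and no knockout count of either gene was left with 10% free RNA subtracted. Of 22 contractile genes 3 were at least 1.5-fold higher, Tagln at 1.69 (1.48 to 1.92) and the actin gene Acta2 at 1.51 (1.34 to 1.72) among them, and 19 lay within 1.5-fold.

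In macrophage and dendritic-like nuclei, Dusp1, a phosphatase of MAP kinases, had a ratio of 21 (9.46 to 58.0), Rgs1, a regulator of G protein signalling, 13.7 (9.16 to 21.4), and the transcription factor Klf2 22.9 (7.63 to 113) from 3 and 100 counts. Lower in the knockout library were the phosphodiesterase Pde7a at 0.388 (0.256 to 0.579), the noncoding RNA Meg3 at 0.100 (0.0564 to 0.167), with 88.9% of its wild-type counts in 1 nucleus, and the epithelial genes Pigr at 0.339 (0.211 to 0.532) and Oit1 at 0.461 (0.332 to 0.638). Over all nuclei outside the epithelium, Pigr stood at 176 CPM in the wild-type and 115 CPM in the knockout library and Oit1 at 249.9 and 215 CPM, which is the level of free RNA for them. Without doublet removal the ratios were 0.815 for Pigr, 0.871 for Oit1, 0.181 for Meg3 and 13.5 for Klf2. With the stricter filter they were 0.746, 0.990 and 0.551 for the first 3 and 8.90 for Rgs1. With 10% free RNA subtracted no knockout count of Pigr or Meg3 was left, and the Oit1 ratio was 0.0328.

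Some genes were apart in the same direction, by at least 1.5-fold, in every class with enough counts. The 5 highest by median log2 ratio were Egr1 (5.56), Fos (3.85), Nr4a1 (3.55), Dusp1 (2.77) and Sgk1 (2.66). With genes named only as clones passed over, the 5 lowest were Tef (-1.36), Nr1d1 (-1.19) and Nr1d2 (-0.98), all of the circadian clock or under its control, the zinc finger gene Zscan29 (-0.82), and Pigc (-0.80), which acts in the synthesis of membrane anchors. Lower than Tef among the clones were Gm47283 (-3.39), which lies on chromosome Y, and 2810405F17Rik (-1.47). Over all nuclei Tef had a ratio of 0.378 (0.338 to 0.423), Nr1d1 0.408 (0.356 to 0.466), Nr1d2 0.507 (0.475 to 0.541), Zscan29 0.558 (0.502 to 0.620) and Pigc 0.590 (0.521 to 0.668).

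The third comparison followed gene lists close to the function of Pink1. Genes of mitophagy, the removal of mitochondria, stood near 0: of 34 members in goblet-like nuclei 30 lay within 1.5-fold (median log2 ratio -0.11), as did 31 of 32 in crypt-base and proliferating, 27 of 34 in colonocyte-like, 27 of 33 in fibroblast-like, 21 of 24 in smooth muscle-like and 11 of 13 in macrophage and dendritic-like nuclei. No reported median of this list left the central 95% of its random lists. In thinned nuclei the macrophage and dendritic-like one was 0.56 and the goblet-like one 0.079, both above the range of the reported setting. Without Malat1 and rRNA-like transcripts the fibroblast-like one was -0.20, but that setting shifts all log2 ratios of the class, random lists included, by -0.051. In colonocyte-like nuclei the mitophagy receptor Bnip3l had a ratio of 0.487 (0.402 to 0.590) and the mitochondrial fusion gene Mfn2 1.57 (1.27 to 1.95). Genes of the nuclear-encoded respiratory chain were slightly higher in the 3 named epithelial classes compared, which leave out the unnamed epithelial clusters. Their medians were 0.19 in goblet-like (percentile 100), 0.098 in crypt-base and proliferating (percentile 99.8, but 0.060, inside the random range, in thinned nuclei) and 0.29 in colonocyte-like nuclei (percentile 100). In goblet-like nuclei 9 of 76 members were at least 1.5-fold higher and 1 as much lower, in colonocyte-like nuclei 6 were higher and none lower, and Sdhb, a subunit of complex II, had ratios of 2.19 (1.56 to 3.12) and 2.57 (1.75 to 3.85). In fibroblast-like, smooth muscle-like and macrophage and dendritic-like nuclei the medians were -0.090, -0.12 and -0.26, within the random range. These 3 did not keep their direction: the fibroblast-like one was 0.066 without doublet removal and 0.19 in thinned nuclei, the smooth muscle-like one 0.17 in thinned nuclei but -0.25 with 10% free RNA subtracted, and the macrophage and dendritic-like one 0.14 with the stricter filter.

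Mitochondrially encoded transcripts, which can mark cytoplasm carried with nuclei, moved with these values. Whether they did so here or differed with the genotype was not measured. They took 0.142% of wild-type and 0.276% of knockout UMIs in goblet-like nuclei. In crypt-base and proliferating nuclei they took 0.144% and 0.223%, and in colonocyte-like nuclei 0.381% and 0.618%. The shares were 0.399% and 0.418% in fibroblast-like and 0.169% and 0.161% in smooth muscle-like nuclei. In the unnamed epithelial nuclei they took 0.484% and 1.34%, a ratio of 2.76. Of 13 such genes in goblet-like nuclei 12 were at least 1.5-fold higher (median log2 ratio 0.96), and mt-Nd2 had a ratio of 2.58 (2.13 to 3.13). Genes of mitochondrial biogenesis and dynamics had medians from -0.20 to 0.023, within the random range in all 6 classes, and Ppargc1a, a coactivator that drives biogenesis, had a ratio of 0.631 (0.543 to 0.733) in goblet-like and 0.650 (0.591 to 0.715) in colonocyte-like nuclei. The mitochondrial stress list had medians from 0.040 to 0.28. In goblet-like nuclei it was 0.32 in those without a mitochondrial UMI and 0.24 in thinned ones, both above its random range. It stood apart from its random lists in fibroblast-like nuclei (percentile 98.6, but inside that range at 0.22 with the stricter filter and 0.16 without doublet removal). There Atf4, a transcription factor of the stress response, had a ratio of 1.90 (1.46 to 2.49) and Ddit4 6.21 (2.87 to 16.0). Antioxidant genes had medians from -0.10 to 0.15, within the random range in all 6 classes (but 0.56 in smooth muscle-like nuclei when thinned), and fatty acid oxidation genes from -0.34 to 0.12, below it in smooth muscle-like nuclei (percentile 0.920; inside it at -0.22 with the stricter filter and -0.19 without doublet removal).

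Lists of immunity and inflammation were higher in several classes of the knockout library. Of 26 interferon response and DNA sensing genes in goblet-like nuclei 9 were at least 1.5-fold higher and none lower (median log2 ratio 0.40), with Rsad2, an antiviral enzyme, at 12.2 (6.80 to 24.1) and Oasl2 at 2.29 (1.70 to 3.1). In colonocyte-like nuclei 12 of 24 were higher and 1 lower (0.59), with the nucleic acid sensor Zbp1 at 3.90 (2.49 to 6.38), and in fibroblast-like nuclei 9 of 22 were higher and 1 lower (0.54), with the DNA sensor Cgas at 0.179 (0.0512 to 0.511). These 3 medians stood at percentile 100, while those in crypt-base and proliferating (0.087, but 0.22 with the stricter filter), smooth muscle-like (0.26) and macrophage and dendritic-like nuclei (0.31, but 0.67 in thinned nuclei) lay within the random range. Both of these alternatives lay above the range of the reported setting. TMM factors gave 0.38 in macrophage and dendritic-like nuclei, but they shift all ratios of a class alike, random lists included. The goblet-like median was -0.071 in nuclei without a mitochondrial UMI, a setting chosen after seeing the data.

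Genes of MHC class I, which present antigen, had medians of 0.39 in goblet-like, 0.31 in crypt-base and proliferating, 0.68 in colonocyte-like and 0.39 in macrophage and dendritic-like nuclei, at percentiles of 100, 99.7, 100 and 98. Of these 4 only the colonocyte-like one stayed above its random range under every alternative, at 0.32 in nuclei without a mitochondrial UMI. There the goblet-like one was 0.058, while the crypt-base and proliferating one was 0.21 at resolution 0.5 and the macrophage and dendritic-like one 0.11 without doublet removal. In colonocyte-like nuclei 7 of 11 were at least 1.5-fold higher, among them the proteasome gene Psmb8 at 5.27 (2.07 to 17.2), and H2-D1 had a ratio of 1.56 (1.39 to 1.76) in goblet-like nuclei. In fibroblast-like nuclei 8 of 9 lay within 1.5-fold. MHC genes have near-identical relatives, so the counts of single members are uncertain. Of 7 MHC class II genes in macrophage and dendritic-like nuclei 1 was at least 1.5-fold higher (median 0.48, percentile 99.0, but 0.055 with the stricter filter). NF-kB and cytokine genes had medians of 0.49 in colonocyte-like, 0.52 in fibroblast-like, 0.59 in smooth muscle-like, 0.43 in macrophage and dendritic-like and 0.18 in goblet-like nuclei, each above its random range, and -0.037 in crypt-base and proliferating nuclei, within it. Only the fibroblast-like one stayed above under every alternative. The median was 0.17 in colonocyte-like nuclei at resolution 2, 0.41 in smooth muscle-like and 0.080 in macrophage and dendritic-like nuclei without doublet removal and 0.040 in goblet-like nuclei with the looser filter, all inside the range. Duox2, which makes hydrogen peroxide at the epithelial surface, had a ratio of 3.44 (2.83 to 4.20) in colonocyte-like nuclei, and the cytokine Il1b 4.36 (2.64 to 7.62) in macrophage and dendritic-like nuclei. The chemokine genes Ccl2 in fibroblast-like and Ccl20 in crypt-base and proliferating nuclei were lower in the knockout library, at 0.252 (0.128 to 0.476) and 0.237 (0.0692 to 0.656).

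Ribosomal protein genes, which make up the translation machinery, had medians of 0.23, 0.16 and 0.13 in goblet-like, crypt-base and proliferating and colonocyte-like nuclei, each above its random range, 0.046 in fibroblast-like and -0.13 in macrophage and dendritic-like nuclei, within it, and -0.32 in smooth muscle-like nuclei, below it (percentile 0.055). In goblet-like nuclei 35 of 37 members lay within 1.5-fold, with the translation factor Eef1a1 at 1.45 (1.33 to 1.59), and in smooth muscle-like nuclei 9 of 37 were at least 1.5-fold lower, with Rps3 at 0.449 (0.219 to 0.902). The smooth muscle-like median was -0.13 without doublet removal and -0.12 in thinned nuclei, both inside the random range, and 0.060 in nuclei without a mitochondrial UMI. In those nuclei the fibroblast-like median was 0.54, above the random range, and without doublet removal the macrophage and dendritic-like one was 0.11. With separate clustering the goblet-like median was 0.044 and the colonocyte-like one 0.077. With the stricter filter the medians were 0.070 in goblet-like and -0.014 in colonocyte-like nuclei, and those of the respiratory chain list 0.064 and 0.10.

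**Figure D3:**
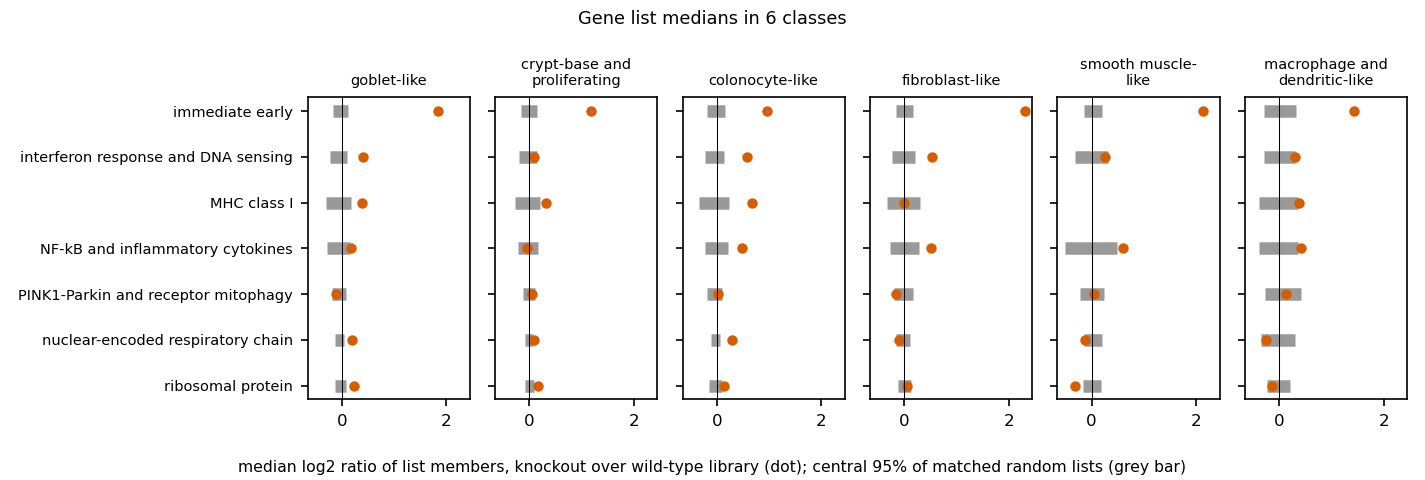
Median log2 ratio (knockout over wild-type library) of 7 gene lists in 6 classes, as dots, with the central 95% of 10000 matched random lists as grey bars; no dot is drawn where fewer than 5 members were measured. The immediate early list lay between 0.96 and 2.31 in the 6 classes and the mitophagy list between -0.15 and 0.14.

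Genes of the circadian clock went both ways. Over all nuclei Arntl, an activator of the clock, had a ratio of 1.41 (1.31 to 1.52), the activators Clock and Npas2 1.02 (0.990 to 1.05) and 1.06 (0.928 to 1.20), Per1, a repressor that also answers to stimuli, 2.71 (2.35 to 3.13), Bhlhe40 1.72 (1.64 to 1.80) and Cry1 1.54 (1.27 to 1.87). The 6 genes taken here as targets of the activators, Nr1d1, Nr1d2, Dbp, Tef, Per3 and Ciart, were lower in the knockout library. Among them were Dbp at 0.178 (0.118 to 0.263), Ciart at 0.365 (0.210 to 0.615) and Per3 at 0.653 (0.615 to 0.692). That choice leaves out Per1, Bhlhe40 and Cry1, which were higher. In colonocyte-like nuclei 4 of 17 measured members were at least 1.5-fold higher and 8 as much lower (median log2 ratio -0.19), and in goblet-like nuclei 3 of 16 were higher and 3 lower (0.29). The medians were 0.37, 0.27, 0.11 and -0.39 in crypt-base and proliferating, fibroblast-like, smooth muscle-like and macrophage and dendritic-like nuclei. A median over members that go both ways gives no direction for the list, and the fibroblast-like one was -0.090 with separate clustering. The labels give the light cycle of the animal room but not the hour of death.

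**Figure D4:**
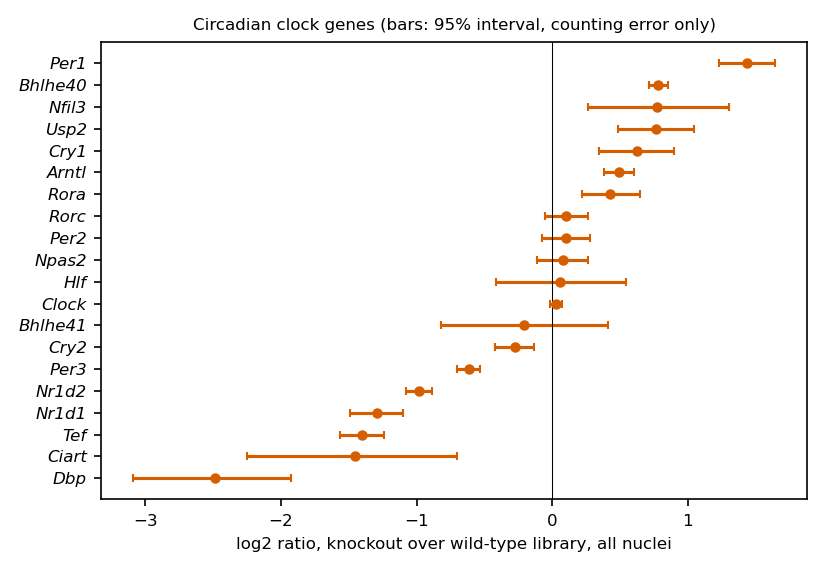
Log2 ratio (knockout over wild-type library) of circadian clock genes over all nuclei, with 95% intervals for counting error only. Per1, Bhlhe40 and Arntl lay above 0, and Dbp, Tef and Nr1d1 below it.

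Lists for tissues that a colon should lack were followed over all nuclei. Cela1, a pancreatic elastase gene that the colon also expresses here, had 1399 and 1905 counts and was among the leading genes of cluster 2, Apob of the small intestine had 167 and 191, Sis 108 and 55, Ttr of the liver 248 and 262, the skeletal muscle gene Mylpf 15 in each library, and the erythrocyte gene Hbb-bs 6 and 14. Both groups were labelled male. The Y-linked genes were present in both libraries and lower in the knockout library, with ratios over all nuclei of 0.517 (0.499 to 0.535) for Ddx3y, 0.563 (0.540 to 0.587) for Uty, 0.474 (0.454 to 0.495) for Kdm5d and 0.547 (0.527 to 0.569) for Eif2s3y, and Xist had 35 and 31 counts. In a check for substrains, Nnt had a ratio of 0.853 (0.748 to 0.973) and Mmrn1 1.13 (0.997 to 1.28), so neither was absent from either library. As with Pink1, tags outside a deleted part of Nnt would remain, so its presence cannot tell whether the substrains differed at that gene.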

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

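The tests of free RNA, of the time of day, of DNA of another origin and of cytoplasmic RNA were chosen only after the results they measure were seen. The test of free RNA replaced an earlier one on the ratio of Errfi1 to Egr1, with the same verdict, and all 4 list differences given last were picked by a rule set after the data were seen. The test of a few induced nuclei was chosen before, set aside once its result was seen and then restored as first worded.

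Immediate early genes were higher in the knockout library in all 6 classes, with median log2 ratios of 0.96 to 2.31. Free RNA from 1 source would keep the genes in 1 proportion in every class if it made up all their counts. For 13 of 17 members with at least 20 counts in both, the shares of the list's counts in goblet-like and fibroblast-like knockout nuclei had intervals apart. This argues against free RNA as the only source of these counts. The shares also carry each class's own expression, so they cannot decide whether free RNA made up the excess over the wild-type library. A few strongly induced nuclei stay open in part. An Egr1 UMI was found at 500 UMIs in 30.3% of goblet-like and 60.6% of fibroblast-like knockout nuclei. Its intervals lay above those of the wild-type library in 5 of 6 classes. In macrophage and dendritic-like nuclei they overlapped, with 5.11% (2.82 to 8.42) in the knockout library. Fos, which was not part of that test, had intervals above those of the wild-type library in all 6 classes. A Fos UMI was found in 0.629% (0.0159 to 3.45) of wild-type and 19.3% (14.8 to 24.5) of knockout macrophage and dendritic-like nuclei. The other members of the list were not counted this way. Another time of day at death stays open. The clock's activators exceeded the targets taken here by at least 1.24 log2 units in each of the 6 classes. Per1, Bhlhe40 and Cry1 were not among these targets, which had been seen lower before the test was written. The activators alone had medians of 0.32 in goblet-like, 0.15 in crypt-base and proliferating and -0.045 in colonocyte-like nuclei. In fibroblast-like, smooth muscle-like and macrophage and dendritic-like nuclei these were 0.37, 0.72 and 0.27. A condition was added after the result was seen, that the activators themselves be higher and the targets lower in each of the 6 classes. The rule had been met before that condition, which the colonocyte-like nuclei did not meet. Handling of the tissue before lysis coincides with library, batch and genotype, so it and a biological effect of the genotype, untested, cannot be told apart.

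Y-linked genes were lower in the knockout library, and so were Zfp990 and Zfp979, which lie on chromosome 4 at 145510759 to 145539188 and 147611937 to 147642513, within 20 Mb of Pink1. Nuclei without a Y chromosome mixed into the knockout library are argued against: 65.1% (64.2 to 66.0) of its nuclei had no Y-linked UMI at 500 UMIs, near the 64.8% of a level lower alike in all nuclei and under the 71.0% of such a mixture. DNA of another origin around Pink1 stays open, because 3 of 51 genes at least 4-fold apart over all nuclei, 5.88% (1.23 to 16.2), lay within 20 Mb of it, against 2.92% of all 14611 measured genes. That share pools 2 of 19 genes lower there (10.5%, 1.30 to 33.1) and 1 of 32 higher (3.12%, 0.0791 to 16.2), too few to decide. The 2 lower ones were Zfp990 and Zfp979, and the higher one was Errfi1, at 150853919 to 150868892. Hnrnpr, named above as lower in fibroblast-like nuclei, also lies in that window, at 136310942 to 136359447. Usp9y, a further Y-linked gene singled out after its values were seen, had 57 and 0 counts, at least 23.4-fold lower in the knockout library against a floor of 3 counts over the library, and an origin of the Y chromosome other than that of the wild-type mice was not tested.

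Respiratory chain and ribosomal protein genes were slightly higher in the named epithelial classes of the knockout library. The unnamed epithelial clusters were left out of these tests. Another mix of clusters within each class is argued against, since with clusters weighted alike the respiratory chain medians were 0.22, 0.12 and 0.24 in goblet-like, crypt-base and proliferating and colonocyte-like nuclei, the lowest of them 0.12, all above their random ranges. Cytoplasmic RNA carried with the nuclei stays open: with the mitochondrial share matched the medians were 0.036, 0.026 and 0.19 (colonocyte-like nuclei still at 0.445% and 0.548% mitochondrial UMIs), of which the lowest, 0.026 in crypt-base and proliferating nuclei, lay inside its random range and the other 2 above theirs. The matched ribosomal medians of -0.018, 0.066 and 0.027 all lay within their random ranges, although the colonocyte-like ribosomal median was 0.33 in nuclei without a mitochondrial UMI, so for that list cytoplasmic RNA cannot be told apart from the genotype. Matching on the mitochondrial share would also take out mitochondrial RNA that differed with the genotype, so it cannot separate that from carried cytoplasm. The genotype is the biological explanation the design gives, and it was not tested.

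The median of a list lay above its random range in 1 class and below it in another in 4 cases, and none of these differences was tested. Glycolysis genes differed by 0.63 log2 units between crypt-base and proliferating (0.25, but 0.071 with separate clustering) and smooth muscle-like nuclei (-0.38, but -0.078 without doublet removal). Ion and water transport genes differed by 2.09 between goblet-like (0.13, but -0.16 with separate clustering) and macrophage and dendritic-like nuclei (-1.96; the macrophage and dendritic-like median was 0.26 without doublet removal and 0.27 with the stricter filter, and Muc2 as the level of free RNA stood at 649 and 482 CPM there). Mucus and secretory genes differed by 0.57 between goblet-like (0.24) and smooth muscle-like nuclei (-0.32, but 0.29 without doublet removal), where Muc2 stood at 543 and 348 CPM against 16083 and 15561 CPM in goblet-like nuclei and 675 and 509 CPM over all nuclei outside the epithelium, which is the level of free RNA. Ribosomal protein genes differed by 0.55 between goblet-like (0.23, but 0.044 with separate clustering and 0.070 with the stricter filter) and smooth muscle-like nuclei (-0.32, but -0.13 without doublet removal, -0.12 in thinned nuclei and 0.060 without a mitochondrial UMI).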

How the results depend on the processing

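The settings without Malat1 and rRNA-like transcripts and in nuclei without a mitochondrial UMI (2126 wild-type and 1060 knockout nuclei, lists only) were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library. Of the list medians under all alternatives 1539 stayed as near to the reported median as the random range extends to either side of its middle, 108 moved further and 12 changed sign after standing apart. Of ratios of named genes 678 stayed within their interval, 52 moved and 2 crossed 1 after an interval without it, and of share ratios 101 stayed, 23 moved and 7 crossed 1 likewise. A further 8 share ratios, counted as stayed or moved, crossed 1 from an interval that included it. The immediate early medians lay between 0.74 and 3.97 in all 15 settings, above the highest upper bound of their random ranges, 0.32. TMM and median-of-ratios factors raised log2 ratios by up to 0.083 (colonocyte-like) and 0.095 (goblet-like nuclei). Other minimum counts per gene alter no ratio and gave no value. Depth limits the macrophage and dendritic-like class most, with 159 and 274 nuclei. Of the 52 moved gene ratios 30 lay nearer to 1 and 22 further from it. Of 47 list medians outside their random range, 30 lay inside it under at least 1 alternative, and of 82 inside theirs 43 lay outside it. These counts use the random ranges of the reported setting. TMM, median-of-ratios factors and CPM without Malat1 and rRNA-like transcripts shift all ratios of a class alike, random lists included. A crossing in those settings does not move a list against its random lists. Values that changed sign or crossed 1 after standing apart follow by setting, with those of Pink1, the class shares and the main gene lists that moved; other moved values are left out, classes are in short form, and the cause was not tested.

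With 10% free RNA subtracted, list medians were immediate early 0.77 in crypt, 0.74 in colonocyte and 1.93 in macrophage, circadian clock 0.16 in crypt. With Scrublet's own threshold, share ratios were 0.979 for crypt and 0.711 for enteric neuron. With the libraries clustered separately, share ratios were 0 for B, 0.765 for crypt, 0 for enteric neuron, 1.58 for goblet and 0.612 for unnamed. There, list medians were respiratory chain 0.058 in goblet, ribosomal protein 0.044 in goblet and 0.27 in crypt, ion transport -0.16 in goblet, anterior Hox 1.11 in goblet, immediate early 0.95 in crypt, circadian clock 0.17 in crypt and -0.090 in fibroblast. With list members of at least 100 counts, list medians were immediate early 0.95 in crypt, 3.30 in fibroblast, 3.14 in muscle and 3.34 in macrophage, circadian clock 0.12 in crypt, NF-kB 0.27 in colonocyte. With the looser filter, share ratios were 1.20 for enteric neuron and 0.647 for unnamed. There, list medians were respiratory chain 0.47 in colonocyte, ribosomal protein 0.55 in colonocyte. With the stricter filter, share ratios were 0.518 for B, 1.17 for blood endothelium, 1.14 for colonocyte, 1.04 for crypt, 0.811 for enteric neuron, 1.19 for fibroblast and 1.81 for interstitial. There, list medians were respiratory chain 0.064 in goblet, 0.10 in colonocyte and 0.14 in macrophage, ribosomal protein 0.070 in goblet and -0.014 in colonocyte, cell cycle -0.025 in crypt, immediate early 1.20 in colonocyte, 2.53 in fibroblast, 2.32 in muscle and 2.12 in macrophage, circadian clock 0.26 in macrophage, ion transport 0.27 in macrophage. With median-of-ratios factors, list medians were respiratory chain 0.29 in goblet. Without doublet removal, share ratios were 0.691 for enteric neuron and 0.693 for unnamed. There, list medians were respiratory chain 0.066 in fibroblast, immediate early 2.86 in muscle, ribosomal protein -0.13 in muscle and 0.11 in macrophage, mucus 0.29 in muscle, ion transport 0.26 in macrophage. There, the Slc26a2 ratio in muscle nuclei was 1.00. In nuclei thinned to 500 UMIs, list medians were mitophagy 0.079 in goblet, 0.083 in fibroblast and 0.56 in macrophage, circadian clock 0.11 in crypt, -0.00067 in fibroblast and -0.21 in muscle, immediate early 2.69 in fibroblast, 3.97 in muscle and 2.42 in macrophage, respiratory chain 0.19 in fibroblast and 0.17 in muscle, ribosomal protein -0.12 in muscle, interferon 0.67 in macrophage. There, the Pink1 ratio in goblet nuclei was 0.238. In nuclei without a mitochondrial UMI, list medians were immediate early 2.12 in goblet, 3.21 in fibroblast and 3.1 in muscle, interferon -0.071 in goblet, MHC class I 0.058 in goblet and 0.32 in colonocyte, circadian clock 0.51 in goblet and 0.082 in crypt, mitophagy -0.076 in crypt, ribosomal protein 0.33 in colonocyte, 0.54 in fibroblast and 0.060 in muscle. At resolution 0.5, share ratios were 1.12 for colonocyte, 1.12 for enteric neuron and 0.924 for unnamed. There, list medians were NF-kB 0.24 in colonocyte, circadian clock -0.47 in colonocyte. At resolution 2, share ratios were 0.976 for colonocyte, 1.07 for crypt, 0.751 for goblet and 0.943 for unnamed. There, list medians were immediate early 1.6 in goblet, respiratory chain 0.28 in goblet, cell cycle -0.057 in crypt, NF-kB 0.17 in colonocyte, circadian clock -0.47 in colonocyte. There, the Iigp1 ratio in colonocyte nuclei was 0.414. Within compartments, share ratios were 1.18 for blood endothelium, 1.04 for fibroblast, 0.95 for interstitial, 0.839 for lymphatic and 0.959 for smooth muscle.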

Other observations

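The lists and their random lists in this part were fixed before the data were examined, no explanation was tested, and the split of the Hox counts by cluster was chosen only after the list's median was seen. Posterior Hox genes, which pattern the distal gut, were lower in the colonocyte-like nuclei of the knockout library: all 6 measured members were at least 1.5-fold lower (median log2 ratio -1.06, percentile 0, but -0.32 with the looser filter, inside the random range), Hoxd13 at 0.440 (0.326 to 0.591) and Hoxa10 at 0.384 (0.257 to 0.565). In the other named classes with 5 measured members the medians lay within the random range, from -0.24 in smooth muscle-like to 0.11 in crypt-base and proliferating nuclei, but with separate clustering they were -0.72 in goblet-like and 0.34 in crypt-base and proliferating nuclei, outside it. The summed CPM of the list was 45.2 in the wild-type and 15.5 in the knockout library in colonocyte-like cluster 6, 18.3 and 27.8 in cluster 7, 485 and 407 in cluster 8 and 209 and 95.2 in cluster 12. Cluster 8 held 531 of 1399 wild-type and 433 of 2265 knockout nuclei of the class, so the class value also carries the mix of clusters. More anterior Hox genes had medians of -0.32 in goblet-like (percentile 0.420) and -0.32 in crypt-base and proliferating nuclei (percentile 0.0400), where Hoxa3 had a ratio of 0.782 (0.699 to 0.874). The goblet-like median was 1.11 when the libraries were clustered separately and -0.14 without doublet removal, and the crypt-base and proliferating one -0.12 in thinned nuclei, the last 2 inside the random range.

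Enteric neuron-like nuclei were too few for values within the class, so transmitter genes were followed over all nuclei. Nos1, which makes nitric oxide, had 65 and 30 counts, a ratio of 0.375 (0.235 to 0.587), Chat, of acetylcholine synthesis, 0.740 (0.529 to 1.03), and the peptide gene Vip 0.665 (0.385 to 1.14). Neuron-like nuclei numbered 16 and 4, and the direction of their share depended on the filter and the clustering. The serotonin transporter gene Slc6a4 had a ratio of 0.587 (0.491 to 0.701) and the vesicular amine transporter gene Slc18a2 1.31 (1.14 to 1.5). Penk, which encodes enkephalin, had 18 and 58 counts, a ratio of 2.62 (1.52 to 4.73). In the 4 named classes with 5 measured members the median of that list ran from -0.28 in crypt-base and proliferating to 0.78 in fibroblast-like nuclei (percentile 98.7; inside the random range at 0.42 without doublet removal).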
